A study of Arabidopsis thaliana with 4 samples.

How the data were processed

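Messenger RNA was sequenced from whole 14-day-old Arabidopsis thaliana seedlings grown on soil, with a stranded library kit, per the labels' protocols. There were 4 libraries, 2 of Col-LUC and 2 of tho2-8. The group was read from each library's title, because the genotype label gives the background line for all 4. Nothing in the labels says whether replicates came from separate plants or cultures, so p-values measure the spread between these libraries, which may be technical.

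The deposited values are estimated counts per gene locus, 1 table per library, not normalised. Per the submitters' processing notes, the tools were Trimmomatic, HISAT2 2.1.0, featureCounts 1.6.3 and DESeq2 1.24.0 with the TAIR10 build. Their settings, including strand and the treatment of shared reads, are not given in the sources used here. About 2.1% of loci in each deposited table hold fractional estimated counts, so values were rounded to whole numbers before the count tests. The design had assumed whole counts. Because the use of strand in counting is not given, values of genes that overlap a gene on the other strand are uncertain. Among genes with values given here these are AT2G30766, CYP71A13, CAO, PORB, CRD1, RVE1, EBF2, FER1, FRO3, CASP1, AFB3, SPL6, UAP56B, MOS11, TCH2, TEX1 and ALY4. Copies such as LHCB1.1 and LHCB1.2 are uncertain for shared reads.

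Each table lists 37869 loci. The 296 plastid and mitochondrial loci hold 0 counts in every library, so organelle-encoded genes are not analysed here. All 37573 nuclear loci matched the TAIR10.1 annotation, from which symbols and the position of THO2 were taken; TAIR10.1 is the reference used here and TAIR10 the build in the notes. The tables hold no coordinates. Totals ran from 17119534 to 17877941 counts, and 3 counts correspond to 0.168 to 0.175 CPM. These floors cover counting error only. Intervals given for list medians and for an odds ratio are taken over genes, which are not independent replicates. No 2 tables were identical. Replicates differed beyond sampling noise, with a chi-square per gene of 26.0 between the Col-LUC and 23.6 between the tho2-8 libraries.

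Analysis used R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. Genes passing filterByExpr defaults were scaled by TMM and tested with glmQLFit and glmQLFTest with genotype as the only term, at a Benjamini-Hochberg adjusted p under 0.05. Standard errors of log2 fold changes were derived from the F statistic. Gene lists were tested with camera at a preset correlation of 0.01, adjusted over the 37 lists with at least 3 tested members, and again with an estimated correlation and with fry. No list was called with an estimated correlation (smallest adjusted p = 0.924) or by fry's directional test (smallest adjusted p = 0.213). With an estimated correlation, camera rests on the 2 residual degrees of freedom, so it could hardly call any list. MicroRNA targets, with an estimated correlation of 0.019 near the preset 0.01, also had an adjusted p of 0.924 by camera. The values with an estimated correlation therefore do not show whether correlation between genes accounts for the calls. The 33 fixed lists held 648 entries, of which 19 were dropped because the annotation did not pair the symbol with the locus, 7 of them in the THO/TREX list. Lists, tests, alternatives and the rule for named genes were fixed before the data were examined. The annotation classes for histones, ribosomal proteins and transposable elements were narrowed or renamed after their membership was seen and before any list was tested. Seed maturation markers had 0 tested members and microRNA primary transcripts are not analysed here.

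The rule named THO2 and the measured THO/TREX members, the 8 highest and 8 lowest log2 fold changes and the 4 smallest p per direction among genes past the threshold with mean log2 CPM of at least 1 and separated groups, and up to 4 tested members with the smallest p per list. Because 2 genes met those conditions, the same rule was also applied to the 533 DESeq2 calls that met the other conditions, a choice made after the values were seen.

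The tests were checked on simulated data made from the means and library sizes of the 20975 genes, with 200 genes changed and 5 draws. A second model of the spread was added after the first result was seen. With each gene's own dispersion, edgeR made 10.6 false calls of 141 per draw, and with the spread of the prior (4.92 degrees of freedom) it made 3.0 of 50.2. In the same draws the microRNA target list was shifted by 0.5 on the log2 scale. It was called in 5 of 5 draws under both models, and other lists were called 3 times and 1 time over the draws. Genes were drawn independently of each other, so these draws cannot check the preset correlation of 0.01. In the data, estimated correlations of called lists ran from 0.019 for microRNA targets to 0.92 for chlorophyll synthesis. Alternatives were DESeq2, limma-voom, other size factors, other filters on low counts, a replicate block, robust estimation, a 1.5-fold test, nuclear genes alone and leaving out each library.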

Results

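The series measured polyadenylated RNA from whole 14-day-old Arabidopsis thaliana seedlings grown on soil. It compared tho2-8, a mutant of THO2, with its background line Col-LUC. There were 2 libraries of each genotype. Counts assigned to genes summed to 17119534 and 17659035 in the Col-LUC libraries and to 17877941 and 17838028 in the tho2-8 libraries. The first principal component of log2 CPM carried 55.2% of the variance and separated the genotypes, and the second carried 26.1%. On the first, the Col-LUC libraries stood at -39.4 and -35.6 and the tho2-8 libraries at 16.9 and 58.1. The correlation of tho2-8 replicate 1 was 0.979 with Col-LUC replicate 2 and 0.9804 with tho2-8 replicate 2. Root markers and floral organ markers also differed between libraries. The mean log2 level of root markers, relative to the Col-LUC mean, was 0.35 and -0.35 in the Col-LUC libraries and -0.30 and -0.60 in the tho2-8 libraries. Floral organ markers stood at -0.86 and 0.86 in Col-LUC and at -0.27 and -0.27 in tho2-8.

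The comparison asked how the seedling transcriptome of tho2-8 differs from that of its parent line. THO2 encodes a subunit of the THO complex, the part of TREX that couples transcription to mRNA packaging and export. Its mRNA stood at 82.1 and 84.6 CPM in the Col-LUC libraries and at 109 and 100.1 CPM in the tho2-8 libraries. The log2 fold change of THO2 (AT1G24706) was 0.33 ± 0.15 (SE, n = 2 per genotype), with an adjusted p of 0.34 by edgeR's quasi-likelihood test. The nature of the allele is not given in the sources used here, so this level does not check the labels. The gene lies on chromosome 1 from 8741836 to 8755604 on the plus strand in TAIR10.1, with 34 exons in its longest annotated model. Of the 8 tested THO/TREX members 0 passed over all genes, while 2 had an unadjusted p under 0.05 and DESeq2 called 1. Adjusted over the list alone 1 rose, the RNA helicase gene UAP56B, at 0.79 ± 0.17 on the log2 scale. UAP56A stood at 0.45 ± 0.17, HPR1 at 0.18, ALY4 at 0.13, THO6 at -0.18 and MOS11 at -0.27. TEX1 stood at 0.01 ± 0.22 and turned negative with DESeq2 and with its size factors in edgeR. The list was not called (camera, adjusted p = 0.26). It passed fry's mixed test, which asks whether members change in either direction (adjusted p = 0.0276). That test does not compare members with other genes.

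Among 20975 tested genes, 2 passed edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 1 lower and 1 higher in tho2-8. AT7SL-1 (AT4G02970) has the annotated product 7SL RNA1, the RNA of the signal recognition particle, though the annotation types the locus as protein-coding. AT7SL-1 fell from 80.7 ± 0.86 CPM to 8.65 ± 0.81 CPM (SD, n = 2). Its log2 fold change was -3.22 ± 0.16 (SE), with an adjusted p of 0.00476 by edgeR. ABCC7 (AT3G13100), an ABC transporter of the multidrug resistance-associated subfamily, rose from 13.8 ± 0.66 CPM to 71.3 ± 10.3 CPM (SD, n = 2). Its log2 fold change was 2.37 ± 0.17 (SE), with an adjusted p of 0.029 by edgeR. ABCC7 overlaps the same-strand gene SERAT2;2 by 132 bp in the annotation, and SERAT2;2 stood at 156 CPM in Col-LUC and 116 CPM in tho2-8. limma-voom called AT7SL-1 (adjusted p = 0.0165) and not ABCC7 (adjusted p = 0.066), and edgeR's test against a 1.5-fold change called AT7SL-1 (adjusted p = 0.00663) and not ABCC7 (adjusted p = 0.0538). Without Col-LUC replicate 1 or 2, edgeR's adjusted p was 0.123 and 0.152 for AT7SL-1 and 0.37 and 0.269 for ABCC7.

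**Figure D1:**
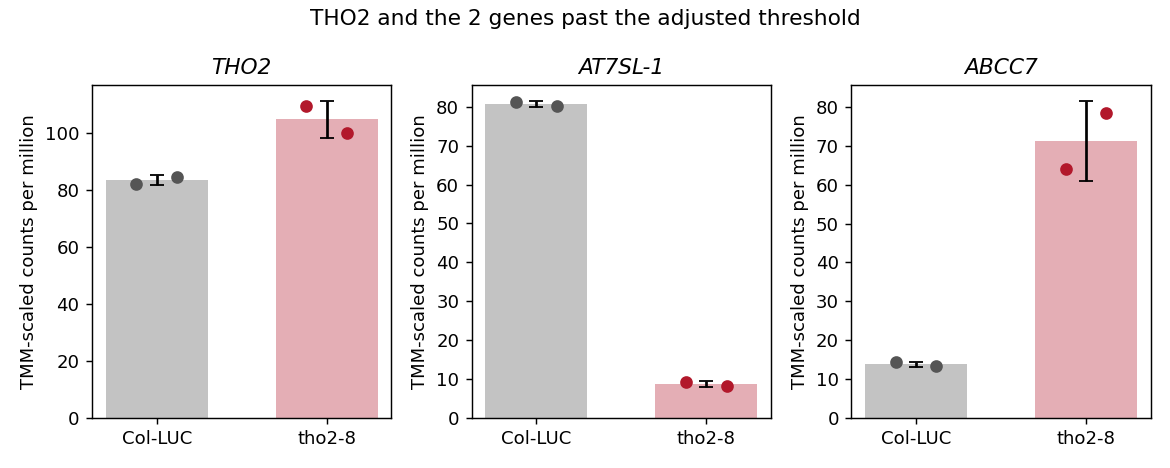
TMM-scaled CPM of THO2, AT7SL-1 and ABCC7 in Col-LUC and tho2-8. Points are libraries, bars the means and whiskers the SD of 2 libraries; AT7SL-1 stands at 80.7 CPM in Col-LUC and 8.65 CPM in tho2-8, and ABCC7 at 13.8 and 71.3 CPM.

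The number of changed genes differed between tools, filters on low counts and sets of libraries. edgeR gave 3269 of the 20975 tested genes at an unadjusted p under 0.05, 1762 higher and 1507 lower. This is the background for the counts at an unadjusted p given for single lists. DESeq2, named in the submitters' processing notes, called 556 genes, 269 higher and 287 lower, including both edgeR genes, from 26203 genes before its own filtering, and limma-voom called 1. Without the filter on low counts edgeR called 57 of 26203 genes. edgeR called 0 genes without Col-LUC replicate 1 (2469 at an unadjusted p under 0.05) and 0 without Col-LUC replicate 2 (2815). It called 701 without tho2-8 replicate 1 and 115 without tho2-8 replicate 2. In simulations of this comparison 200 of 20975 genes were changed singly and the microRNA target list was shifted by 0.5 on the log2 scale. The share of genes changed in the data is not known, and the rates depend on it. With each gene's own spread edgeR recovered 39% of 2-fold and 91% of 4-fold changes. With spread drawn from the prior of the fit it recovered 0.4% and 46.8%. Of the simulated DESeq2 calls, 15.0% and 40.2% were false under those models. Both tho2-8 libraries lay on 1 side of both Col-LUC libraries for 48.5% of tested genes, where chance gives 33.3%.

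The genes described next were called by DESeq2 and not by edgeR. They come from the rule for named genes applied to the DESeq2 calls, a choice made after the values were seen. TPS04, the geranyllinalool synthase, stood at 6.31 and 3.54 CPM in the Col-LUC libraries and at 0.0559 and 0 CPM in the tho2-8 libraries. ELI3-2, a pathogen-inducible alcohol dehydrogenase, stood at 5.06 CPM in Col-LUC and 0.278 CPM in tho2-8. CYP71A13, of camalexin synthesis, stood at 3.72 and 0.223 CPM. NATA1, an acetyltransferase, had a log2 fold change of -3.15 ± 0.34. The non-coding RNA AT3G05945 stood at 12.3 and 0.248 CPM. AT3G01345, an uncharacterized protein gene, stood at 0.0573 and 0.295 CPM in the Col-LUC libraries and at 11.4 and 40.3 CPM in the tho2-8 libraries. AT2G30766, which overlaps CYP71A13 on the opposite strand, stood at 0 and 0.295 CPM in Col-LUC and at 6.49 and 5.72 CPM in tho2-8. WRKY49 stood at 0.618 and 5.54 CPM, and the protein phosphatase gene AT5G01700 at 3.46 and 17.8 CPM. edgeR gave these genes adjusted p between 0.0858 and 0.164.

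Genes of the touch and rapid handling response rose together in tho2-8 (camera, adjusted p = 8.4e-20), with a median log2 fold change of 1.39 over 15 tested members. The adjusted p was 0.924 with an estimated correlation, a setting with 2 residual degrees of freedom in which no list was called. Adjusted over the list alone 14 rose and 0 fell. Over all genes 0 passed in edgeR, while 14 were higher at an unadjusted p under 0.05 and DESeq2 called 7 higher. ZAT10 and ZAT12, zinc finger proteins of early stress responses, stood at 26.3 and 153 CPM and at 9.49 and 44.9 CPM in Col-LUC and tho2-8. TCH4, a xyloglucan endotransglucosylase, stood at 29.7 and 101 CPM, and TCH2, a calmodulin-like protein, at 33.8 and 78.6 CPM. The mean of the list was -0.08 and 0.08 in the Col-LUC libraries and 0.98 and 1.66 in the tho2-8 libraries. Ethylene signalling genes rose as well (camera, adjusted p = 2.25e-05, median 0.45, 21 tested members; adjusted p = 0.924 with an estimated correlation). Of these 7 rose adjusted over the list alone, over all genes 0 passed in edgeR, 10 were higher at an unadjusted p under 0.05 and DESeq2 called 4. ERF4 had a log2 fold change of 0.97 ± 0.16, ACS6, which makes the ethylene precursor, of 1.21 ± 0.27, and EBF2 of 0.74 ± 0.21. Some members also belong to the touch list, and without them, a choice made after seeing the data, the adjusted p was 0.000371 by camera. Root markers had a median of -0.58 beside these lists (camera, adjusted p = 0.0521).

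Genes of the salicylic acid and immune response fell in tho2-8 (camera, adjusted p = 1.18e-05), with a median log2 fold change of -0.30 and a mean of -0.92 over 26 tested members. The adjusted p was 0.924 with an estimated correlation. The list median, relative to the Col-LUC mean, was -0.14 and 0.14 in the Col-LUC libraries. It was -0.20 and -0.66 in tho2-8 replicates 1 and 2. Adjusted over the list alone 9 fell and 1 rose. Over all genes 0 passed in edgeR, while 9 were lower and 1 higher at an unadjusted p under 0.05 and DESeq2 called 7 lower and 1 higher. PR1, a marker of the salicylic acid response, stood at 117 and 186 CPM in the Col-LUC libraries and at 6.32 and 0.055 CPM in the tho2-8 libraries, and neither edgeR (adjusted p = 0.126) nor DESeq2 (adjusted p = 0.169) called it over all genes. PR2, a glucanase, stood at 91.7 and 55.3 CPM and at 11.1 and 2.25 CPM. PR5 had a log2 fold change of -2.64 ± 0.56 and PCC1 of -2.27 ± 0.39. Senescence and starvation genes fell too (camera, adjusted p = 0.00298, median -0.42, 19 tested members; adjusted p = 0.936 with an estimated correlation). In this list 2 fell adjusted over the list alone, over all genes 0 passed in edgeR, 3 were lower at an unadjusted p under 0.05 and DESeq2 called 1. The median of the senescence list was -0.21 and 0.21 in the Col-LUC libraries and -0.27 and -0.69 in the tho2-8 libraries. SAG13 stood at 71.8 and 60.8 CPM in Col-LUC and at 14.5 and 1.92 CPM in tho2-8, and SEN4 at 255 ± 32.3 and 123 ± 38.5 CPM (SD, n = 2). Over all genes SAG13 was called by neither edgeR (adjusted p = 0.16) nor DESeq2 (adjusted p = 0.215). Without Col-LUC replicate 2 the senescence list was not called (adjusted p = 0.31). The median of the root markers, -0.58, was also below 0.

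Genes of nitrate uptake and assimilation fell (camera, adjusted p = 0.000303, median -0.81, 4 tested members; adjusted p = 0.924 with an estimated correlation). Of these 3 fell adjusted over the list alone, over all genes 0 passed in edgeR, 3 were lower at an unadjusted p under 0.05 and DESeq2 called 3. The nitrate reductase gene NIA1 had a log2 fold change of -0.99 ± 0.23, the transporter NRT1.1 of -0.85 ± 0.23, the nitrite reductase NIR1 of -0.77 ± 0.25 and NIA2 of -0.51 ± 0.38. Photosynthesis genes were called higher by camera (adjusted p = 0.000474, median 0.22, 31 tested members), with an adjusted p of 0.936 at an estimated correlation. The list median, relative to the Col-LUC mean, was -0.26 and 0.26 in the Col-LUC libraries. It was 0.31 and 0.16 in the tho2-8 libraries, so the genotypes overlapped. Adjusted over the list alone 2 rose, LHCB1.1 at 1.69 ± 0.18 and LHCB1.2 at 1.26 ± 0.16 on the log2 scale. Over all genes 0 passed in edgeR, 6 were higher at an unadjusted p under 0.05 and DESeq2 called 2. The counting could divide reads between these near-identical copies, and without such copies, a choice made after seeing the data, the list was not called (adjusted p = 0.0862). Chlorophyll synthesis genes rose (camera, adjusted p = 0.0163, median 0.40, 9 tested members; adjusted p = 0.936 with an estimated correlation), with CAO at 0.71 ± 0.19, PORB at 0.63 ± 0.23 and CRD1 at 0.57 ± 0.23. In this list 0 members passed in edgeR over all genes or adjusted over the list alone, 3 were higher at an unadjusted p under 0.05 and DESeq2 called 0. The median of the chlorophyll list was -0.24 and 0.24 in the Col-LUC libraries and 0.50 and 0.31 in the tho2-8 libraries. Without Col-LUC replicate 1 the adjusted p was 0.615 for photosynthesis and 0.471 for chlorophyll synthesis, and without tho2-8 replicate 1 it was 0.127 and 0.168. Root markers had a median of -0.58 beside these lists, with CASP1 and CASP2 of the root endodermis at -1.33 ± 0.42 and -1.36 ± 0.46. Root markers passed with all 4 libraries scaled by library totals (camera, adjusted p = 0.0466), without Col-LUC replicate 2 and without tho2-8 replicate 1. They did not pass without Col-LUC replicate 1 or without tho2-8 replicate 2.

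**Figure D2:**
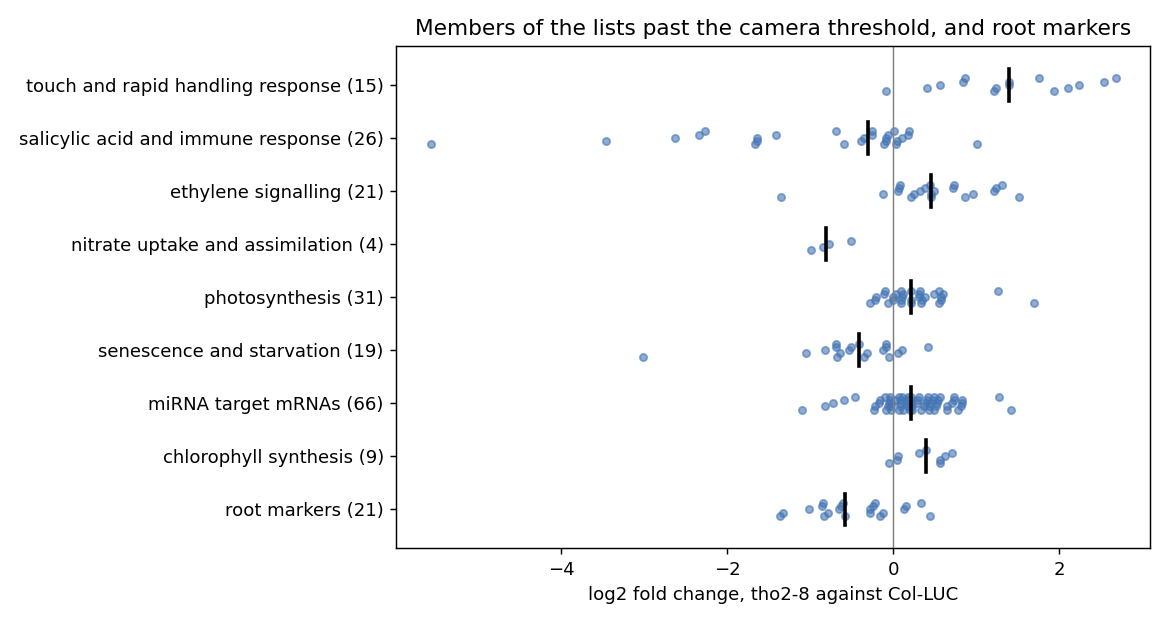
Log2 fold change, tho2-8 against Col-LUC, of each tested member of the 8 called lists and of the root markers. Points are genes, black lines the medians and numbers in brackets the members tested; the median of the touch and rapid handling list is 1.39 and that of the root markers -0.58.

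Messages targeted by microRNAs rose (camera, adjusted p = 0.00298, median 0.21, 66 tested members; adjusted p = 0.924 with an estimated correlation). Over all genes and adjusted over the list alone 0 passed in edgeR, while 19 were higher and 3 lower at an unadjusted p under 0.05 and DESeq2 called 1. The auxin receptor AFB3 had a log2 fold change of 0.82 ± 0.16, ARF8 of 0.56 ± 0.15, SPL6 of 0.65 ± 0.18 and GRF8 of 1.42 ± 0.40. The list passed camera in each fit that left out 1 library, as did the touch, ethylene, salicylic acid and nitrate lists. Root markers had a median of -0.58 in the same comparison. Genes of microRNA biogenesis and turnover had a median of 0.06 (camera, adjusted p = 0.315), siRNA and transcriptional silencing genes of 0.05 (adjusted p = 0.831) and loci and targets of trans-acting siRNAs of 0.11 (adjusted p = 0.395). In these 3 lists edgeR called 0 members over all genes or adjusted over the list alone and DESeq2 called 0, with 3, 2 and 1 members at an unadjusted p under 0.05. By fry's mixed test the microRNA targets, siRNA and trans-acting siRNA lists passed (adjusted p = 0.00563 for each). The touch list did not (adjusted p = 0.122, fry's mixed test). Because that test does not compare a list with other genes, a pass does not set these lists apart. Over all 20975 tested genes, 3269 had an unadjusted p under 0.05 by edgeR.

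The remaining lists did not pass camera with TMM scaling, all 4 libraries, genotype as the only term and members kept by the naming rule. Flowering time genes had a median of 0.30 (adjusted p = 0.0507), and among them MAF5, a MADS-box repressor of flowering, stood at 0.64 and 5.10 CPM in Col-LUC and tho2-8. Anthocyanin and flavonoid genes had a median of 0.17 (adjusted p = 0.0521), with LDOX at a log2 fold change of 1.29 ± 0.25 and MYB75 at 1.42 ± 0.38. Clock genes had a median of 0.18 (adjusted p = 0.0723), and RVE1 stood at 105 ± 25.6 and 226 ± 6.16 CPM (SD, n = 2). Intronless coding genes had a median of 0.12 (adjusted p = 0.0521, 2712 tested), iron homeostasis genes of -0.18 (adjusted p = 0.151) and splicing regulators of 0.10 (adjusted p = 0.372). By fry's mixed test, which does not compare a list with other genes, the iron list (adjusted p = 0.00563) and the splicing regulators (adjusted p = 0.0276) passed. Medians were 0.01 for histones, -0.06 for ribosomal proteins, 0.09 for cell cycle, 0.06 for DNA damage and -0.03 for mRNA decay genes, with adjusted p between 0.423 and 0.952. They were 0.10 for glucosinolate, 0.03 for jasmonate, 0.10 for auxin, 0.16 for cytokinin, 0.06 for heat shock, -0.12 for cold, drought and ABA and 0.11 for phosphate starvation genes, with adjusted p between 0.633 and 0.787. For histones, jasmonate, phosphate and mRNA decay the median, the mean and the test differed in sign. Transposable element genes stood at 0.08 (adjusted p = 0.787) and other non-coding RNA loci at -0.05 (adjusted p = 0.501), which passed fry's mixed test (adjusted p = 0.00563). Among these loci AT4G36648 stood at 198 ± 0.85 CPM in Col-LUC and 70.7 ± 11.5 CPM in tho2-8 (SD, n = 2). Markers of floral organs stood at -0.55, of the stomatal lineage at 0.18, of the shoot meristem at 0.27 and of vascular tissue at 0.10, with adjusted p between 0.512 and 0.787. With library totals in place of TMM, flowering time (adjusted p = 0.0466), anthocyanin and clock genes (0.0499 each) passed. Some of these lists passed with 1 library left out. Without Col-LUC replicate 1 these were intronless genes (adjusted p = 0.0349), cell cycle (0.00129), cold, drought and ABA (0.000537) and floral organs (1.04e-05). Without Col-LUC replicate 2 these were flowering time (adjusted p = 0.0336), anthocyanin (0.0113), clock (0.000398) and ribosomal proteins (0.0175). Without tho2-8 replicate 1 these were flowering time (adjusted p = 0.0184), shoot meristem (0.00775) and glucosinolate synthesis, higher (2.49e-05). Without tho2-8 replicate 2 these were anthocyanin (adjusted p = 0.0101), clock (0.0334), cold, drought and ABA (0.0195), stomatal lineage (0.00844) and glucosinolate synthesis, lower (0.00167).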

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

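The crossed pairing, the list without shared members, the list without near-identical copies, the lists with dropped members put back and RLE for lists were chosen after seeing the data. The count of 2 genes was the same with DESeq2 size factors in edgeR, library totals, a minimum of 10 counts in every library and robust estimation; leaving out organelle loci moved nothing, since they hold 0 counts. With DESeq2, 556 genes were called, 269 higher, 287 lower and 372 at least 2-fold changed. limma-voom and the 1.5-fold test each called 1 gene, lower and at least 2-fold changed, and 0 higher. With no filter 57 were called, 39 higher and 18 lower, all at least 2-fold changed. Leaving out each library gave 0 to 701 changed, 0 to 303 higher, 0 to 398 lower and 0 to 649 at least 2-fold changed genes; the group left with 1 library is then assumed to vary like the other. The cause of these differences was not tested. THO2 kept its direction and did not pass in any setting, with log2 fold changes from 0.24 to 0.40. AT7SL-1 lost its call without either Col-LUC library (adjusted p = 0.123 and 0.152), and ABCC7 there (0.37 and 0.269), by limma-voom (0.066), by the 1.5-fold test (0.0538) and with the replicate block (0.0685), all with the same direction. Over all named genes, 836 repeats kept direction and side of the threshold, 135 passed where the test reported above did not, 7 no longer passed and 4 changed sign. Those 4 were all of the TEX1 log2 fold change, at -0.002 with DESeq2, -0.0052 with DESeq2 size factors (RLE) in edgeR and -0.1942 to 0.185 when 1 library was left out. The 8 called lists became 0 with an estimated correlation and 0 with fry's directional test, and 10 to 13 when 1 library was left out; fry's mixed test called 7 lists, of which the microRNA targets were 1 of these 8. Lists near the threshold passed under other settings: with dropped members put back anthocyanin (0.0386), flowering time (0.0456), root markers (0.049) and intronless genes (0.04998), with RLE flowering time and intronless genes (0.0439 each), and with library totals anthocyanin and clock (0.0499 each) and flowering time and root markers (0.0466 each). A list's direction was counted as reversed where it was called in at least 1 of the 2 fits compared: this held for glucosinolate synthesis, which ranged from 2.492e-05 to 0.9315 in adjusted p when 1 library was left out and was lower without tho2-8 replicate 2 (0.00167). Depth limits genes near 0.168 to 0.175 CPM, the level of 3 counts.

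Same-numbered libraries deviated from their group means with a correlation of -0.12, and the labels do not tie the numbers to a batch. With the replicate block 2 genes were called, 1 higher, 1 lower and 2 at least 2-fold changed, of which 1 was shared with the fit without it; 11 lists were called, with anthocyanin (0.0222), flowering time (0.039) and root markers (0.0097) added, and THO2 stood at 0.33. The crossed pairing called 510 genes, 270 higher, 240 lower and 299 at least 2-fold changed.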

Other observations

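Among the tests here, those on a time of day and on upstream neighbours in general were written before their results were seen, and the others after. The iron homeostasis list held members that went both ways. The ferritins FER1 and FER3, which store iron, stood at log2 fold changes of -1.11 ± 0.20 and -0.89 ± 0.16, and PYE, a regulator of the iron deficiency response, at 0.86 ± 0.20 (SE, n = 2 per genotype). FRO3, a reductase gene that iron deficiency induces, stood at -0.45 ± 0.14. FER1 and FRO3 overlap genes on the opposite strand, so their values are uncertain. edgeR gave these 4 genes adjusted p between 0.125 and 0.231, and DESeq2 called the 2 ferritins. The list was not called by camera (adjusted p = 0.151) and passed fry's mixed test (adjusted p = 0.00563), and with the dropped members put back its adjusted p by camera was 0.885. AT2G30766 is the locus of IMA3, a small peptide of iron signalling, which the naming rule had dropped, and it overlaps CYP71A13 on the opposite strand. To test a coordinated iron deficiency response, 10 genes were picked after the values were seen. IMA1, BHLH38, BHLH39, BHLH100 and BHLH101 did not pass the filter on low counts. The 5 tested genes lay on the predicted side, which is no independent support because the values had been seen. IMA2 had an unadjusted p of 0.108 (edgeR), and DESeq2 called IMA3, FER1 and FER3 but not IMA2 or FER4. FRO3 was not among the 10 and lay on the other side (unadjusted p = 0.0176, edgeR), so whether such a response may underlie these values stays open. Floral organ markers varied within Col-LUC, with AP1 at 2.0 and 10.6 CPM. In glucosinolate synthesis, MYB28 had a log2 fold change of 1.07 ± 0.32. CMT2, a DNA methyltransferase, stood at 0.54 ± 0.14.

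The touch and rapid handling list was higher in tho2-8. A single tho2-8 library handled differently is argued against as the whole cause. Without tho2-8 replicate 2, the library with the higher list mean, 62.1% of the list median remained (95% bootstrap interval over members 50.1 to 83.4). The cut was 50%, written after the values were seen, and the lower end barely clears it. The interval does not measure the spread between libraries. A different handling of the genotypes at harvest cannot be told apart from the mutation, because both would place every tho2-8 library above every Col-LUC library, here by 0.90 on the log2 scale. For a different time of day, dawn and dusk clock genes differed by 0.029 in median log2 fold change, and the 95% interval of -0.19 to 0.79 over 3 genes in each set passes the bound of 0.5 set beforehand. This stays open too, as does an effect of the mutation, which was not tested apart from handling.

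AT7SL-1 was lower in tho2-8. A smaller carry-over of RNA without poly(A) tails could lower it, if its counts come from such RNA. The 58 tested rRNA, snRNA, snoRNA and tRNA loci had a median log2 fold change of -0.19 (quartiles -0.52 and 0.16). Of these 51 were snoRNA, 3 rRNA, 1 snRNA and 3 tRNA loci. The median argues against a general loss at snoRNA loci, and the other classes held too few loci to tell. An effect of the mutation, a difference at the locus between the lines and reads shared with other loci stay open and were not tested. The annotation types the locus as protein-coding, and whether its counts come from 7SL RNA was not tested either.

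ABCC7 was higher in tho2-8. Reads shared with its paralogs ABCC3 and ABCC6 are argued against, since these lost 0.562% (SD 17.9) of the CPM that ABCC7 gained. For transcription running on as a general effect, same-strand neighbours that start upstream were counted. They had to end within 500 bp upstream of the gene or inside it. Such a neighbour was found for 54 of the 268 genes that DESeq2 called higher among those edgeR tested. It was found for 5335 of 20707 other tested genes (odds ratio 0.727, 95% interval 0.528 to 0.986, Fisher's exact test). Genes called higher were thus not enriched for such neighbours, which argues against a general effect. Neighbours were counted whether or not they are expressed, which weakens the test. Run-on from SERAT2;2 alone may still account for the higher ABCC7. The change of SERAT2;2 was -25.6% of its CPM, and without read positions this cannot be told apart from a change of ABCC7 itself.

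Other hypotheses were tested once each. A linked stretch of another parent's genome could place called genes together. Over 121 windows of 1 Mb the smallest adjusted p was 0.609 for DESeq2 calls (hypergeometric test). The test counts calls whatever their size, so it cannot exclude a short stretch that holds few called genes. Genes without introns may differ between the genotypes: their median exceeded that of intron-containing genes by 0.12 in tho2-8 against Col-LUC, 2.46 times the larger of the differences between replicates, which were -0.05 and 0.04. This is a hypothesis found and tested on the same 4 libraries.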
